A study of Mus musculus with 8 samples.

How the data were processed

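Total RNA was sequenced from primary astrocyte cultures grown from the retinas and optic nerves of newborn mice, 4 samples labelled wild type and 4 labelled Spp1 knockout. Cells were kept in DMEM/F12 medium with fetal bovine serum, and RNA was purified with a column kit before library preparation at a sequencing company, per the labels' protocols. The labels number the samples within a genotype and give no litter, batch or sex, and they do not say whether the 4 samples of a genotype came from separate cultures. P-values of single genes therefore measure only the spread between these samples, which may be technical. P-values of the gene lists below compare genes with other genes and measure no spread between samples.

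The submitters' processing notes name CASAVA 1.8, STAR 2.7, DESeq2 1.30.1 and the mouse build GRCm38, without saying which step used which. The gene annotation, the counting step and the filters are not given in the sources used here. The values analysed were the authors' deposited table of 1 comparison between the genotypes, with 3624 genes and 0 columns of per-sample values. Per the file headers, the authors gave for each gene a mean normalized count over all samples, a log2 fold change with its standard error on the log2 scale, a Wald statistic, which is a score without fixed range, a p-value and an adjusted p-value. The Wald statistic equalled the log2 fold change divided by its standard error to within 1.51e-07 for every gene. Every adjusted p-value in the deposited table was at most 0.0499 and every absolute log2 fold change at least 0.58, so the table was filtered on both before deposit. From the ratio of adjusted to raw p-values of the 20 genes with the smallest p-values above 0, about 16600 genes were tested and about 5100 passed the adjusted p threshold, which places about 1500 of them below the fold-change limit and outside the table. A gene absent from the table may have missed either limit or may not have been tested, so absence was never read as no change.

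The table does not state the direction of the fold change. Values were read as knockout over wild type because Spp1, the deleted gene, is negative, so the Spp1 value fixes the direction and cannot also test it. Without values per sample no test across samples was possible here, and the planned fit with a count model was replaced by the plan set for a table of comparisons, in which the authors' log2 fold changes and adjusted p-values are counted as deposited. Library totals, the spread between replicates and single outlying samples were out of reach for the same reason, and the depth of each sample is unknown. The standard error of each fold change, with a median of 0.236 on the log2 scale, carries the precision. Group means called implied means were worked out from the mean normalized count and the fold change, taking the groups as equal in size. Intervals at 95% are the log2 fold change plus or minus the normal quantile times the deposited standard error.

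Before the data were examined, 34 gene lists were fixed, covering astrocyte identity and reactivity, other cell types that such cultures could hold, and pathways. For each of the 33 lists with a listed member, the members higher and lower in the knockout were set against the rest of the table with a two-sided Fisher's exact test, and p-values were adjusted over the 33 lists by the Benjamini-Hochberg method with a threshold of 0.05. This tests whether the listed members lean one way more than other changed genes do. It treats genes as independent, whereas genes of one cell type or pathway move together, so its p-values are too small by an unknown amount. A count of members adjusted over the list alone could not be formed, since the authors' deposited table holds p-values for listed genes only. Another 6 lists were chosen after the values were seen. Their counts, with some medians and members, are given without a test in the closing section.

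Named genes followed a rule fixed beforehand: Spp1, the 10 largest rises and 10 largest falls among genes with a mean normalized count of at least 100, without names that are only identifiers or predicted genes, and up to 4 members per list with the smallest adjusted p-value. Some genes that the rule names are not reported here. Other genes named were picked after their values were seen, mostly as the exceptions within a list. The list test was tested on simulated data: in 100 simulated tables of 3624 genes, with 95% of the members of planted lists of at least 20 genes set to one direction, Fisher's exact test found 98.5% of the planted lists and called 0.519% of the unplanted ones. Fold changes were shuffled over genes independently, so these rates do not cover genes that move together. Nor do they cover smaller called lists, such as Müller glia and retinal progenitor markers with 9 listed members. Of the random-list alternatives, only lists matched on mean count with the median log2 fold change were simulated, with fewer draws than for the data. They found 12.0% of the planted lists and called 0.333% of the others.

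Alternatives set before the data were stricter adjusted p and fold-change limits for the counts of genes, minimum mean counts of 10 and 100, Bonferroni adjustment, and, for the lists, 10000 unmatched random lists and lists matched on mean count in 10 bins with the mean or the Wald statistic. Added for the lists after seeing the data were the stricter adjusted p and fold-change limits and matched random lists with the median log2 fold change. Also added then were joint limits on fold change and mean count, matching on GC content and transcript length, leaving out genes shared between lists, leaving out microglia and macrophage markers, and leaving out X-linked and Y-linked genes. Gene positions, transcript lengths and GC content came from GENCODE M21 on GRCm38, where 3583 of the 3624 symbols (98.9%) matched a gene and 3586 (99.0%) a transcript. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.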

Results

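Gene expression was compared between astrocyte cultures from the retinas and optic nerves of newborn Spp1 knockout mice (4 samples) and C57BL/6 wild-type mice (4 samples). Spp1 encodes osteopontin, a secreted phosphoprotein of extracellular matrix that also acts as a cytokine. The comparison asks which transcripts differ between knockout and wild-type cultures. Differences between the mice other than Spp1, such as strain background, were not tested. The depth of each sample is unknown, and the values below are fold changes of knockout over wild type with the standard errors the authors deposited.

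Spp1 itself was the reference point of the comparison. The gene lies on the plus strand of chromosome 5 at 104435118 to 104441050 in GRCm38. In the authors' deposited table Spp1 fell by 5.90 on the log2 scale with a deposited standard error of 0.11, a 59.6-fold lower level (95% interval 51.3 to 69.2). Its implied mean normalized count was 26271 in wild type and 441 in the knockout, worked out from the authors' deposited table. The part of the gene removed in this strain is not given in the sources used here, so the remaining signal was not assigned to a part of the transcript. Dmp1, a neighbour of Spp1 in the same family of matrix phosphoproteins, fell by 2.50 with a deposited standard error of 0.38 in the authors' deposited table.

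The authors' deposited table held 3624 changed genes, of which 1991 were higher and 1633 lower in the knockout. The median absolute log2 fold change was 1.14, and 2101 genes changed by at least 1 on the log2 scale, 1286 of them higher and 815 lower. Changes of at least 3 on the log2 scale were listed for 345 genes, 195 higher and 150 lower. Of the 3583 genes matched to the annotation, 3519 were protein-coding.

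The largest rises in the knockout included Y-linked genes, prostaglandin D genes and Arg1. The authors' deposited table gave Ddx3y and Eif2s3y, which encode an RNA helicase and a translation initiation factor subunit on the Y chromosome, log2 fold changes of 13.26 and 11.71. Both had an implied wild-type mean of 0.16, so the size of these fitted values depends on counts near 0. The lower ends of their 95% intervals were 11.23 and 9.66. The Y-linked genes Uty (6.01, deposited standard error 0.38) and Kdm5d (5.91, 0.25) were also among the 10 largest rises of the authors' deposited table. Sex is not given in the labels, and of 6 listed Y-linked genes 5 were higher and 1 lower. The wild-type level of Ddx3y, Eif2s3y, Uty and Kdm5d was at most 1.66% of the knockout level. Sex and genotype may therefore be confounded for every gene reported here. Ptgds, a prostaglandin D synthase, rose by 5.68 with a deposited standard error of 0.59, and Ptgdr, a prostaglandin D2 receptor, by 6.14 with 0.33, in the authors' deposited table. Arg1, the arginase of the urea cycle, rose by 5.84 (deposited standard error 0.38), Slc22a8, an organic anion transporter, by 5.10 (0.44), Nxpe5 by 6.41 (0.31) and Cd93, a transmembrane receptor, by 4.99 (0.16) in the authors' deposited table.

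The largest falls included genes of myelinating glia and neural crest derivatives. In the authors' deposited table Mag, a myelin-associated glycoprotein, had a log2 fold change of -6.43 (deposited standard error 0.53), Sox10, a transcription factor of oligodendrocytes and Schwann cells, of -5.00 (0.78), and Ngfr, the p75 neurotrophin receptor, of -4.11 (0.21). Lrtm1 stood at -6.00 (0.47) and Meox1, a homeobox transcription factor, at -4.97 (0.43) in the authors' deposited table. Syt4, a synaptotagmin, stood at -4.28 (0.30), Kcna1, a voltage-gated potassium channel, at -4.07 (0.35), Col20a1, a collagen, at -3.65 (0.90), and Sox3 at -3.62 (0.40) in the authors' deposited table.

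**Figure D1:**
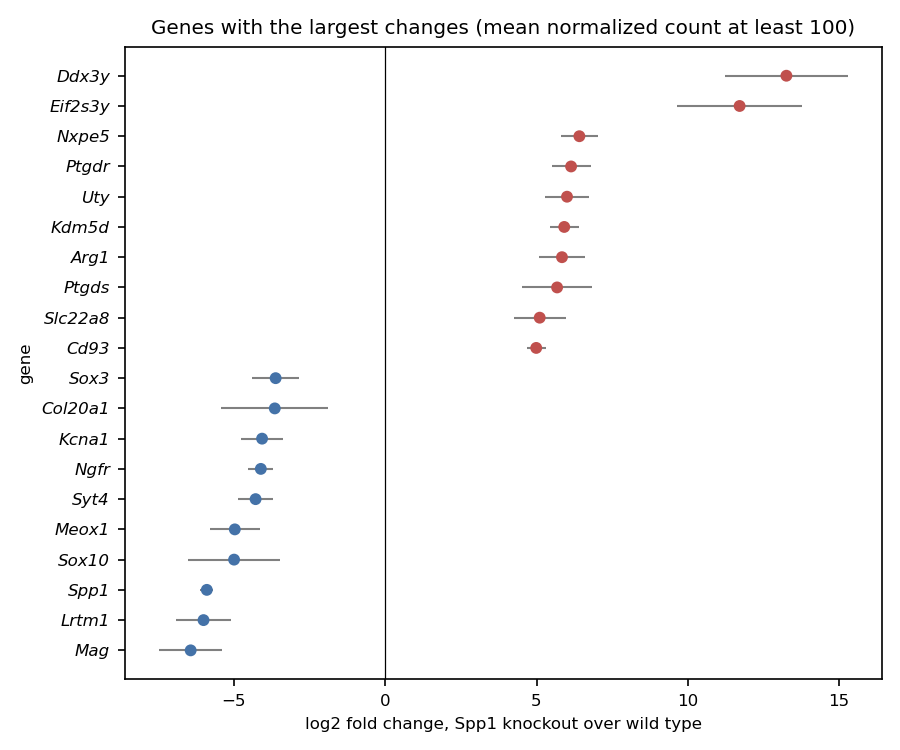
Log2 fold change of knockout over wild type (x axis) for the 10 largest rises and 10 largest falls among genes with a mean normalized count of at least 100, from the authors' deposited table. Points are the deposited values and bars their 95% intervals; rises run from 4.99 (Cd93) to 13.26 (Ddx3y), and Spp1 is among the falls.

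Listed markers of microglia and macrophages were higher in the knockout; for this and every other list, unlisted members were not shown to change. All 25 listed members of this list of 28 genes rose and 0 fell, with a median log2 fold change of 2.25, a 4.75-fold higher level. In the authors' deposited table Mrc1, the mannose receptor, rose by 4.36 (deposited standard error 0.13), Adgre1, which encodes F4/80, by 2.85 (0.13), Itgam, the integrin CD11b, by 2.7 (0.12) and Mpeg1, a perforin-like protein of macrophages, by 2.30 (0.09). The lean of the list toward higher members passed Fisher's exact test (adjusted p = 3.9e-06) and held in all 9 alternatives, with adjusted p up to 0.0022.

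Listed complement genes were mostly higher in the knockout. Of 16 listed genes 15 were higher and 1 lower, with a median log2 fold change of 1.96 (Fisher's exact test, adjusted p = 0.0045). C3, the central complement component, rose by 3.98 (deposited standard error 0.24), and the receptors C3ar1 by 2.79 (0.15) and C5ar1 by 2.26 (0.11) in the authors' deposited table. The lower gene was Masp1, a protease of the lectin pathway, which fell by 0.98 in the authors' deposited table. The macrophage markers, 3 of which are also on the complement list, were higher beside it, and the call was lost (adjusted p = 0.060) when genes on more than one list were left out, the highest value over 10 alternatives that began at 0.0013.

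Listed lysosomal genes were higher, with 24 of 24 listed members of 34 genes raised and a median log2 fold change of 0.90 (Fisher's exact test, adjusted p = 5.6e-06). In the authors' deposited table Cd68, a lysosomal membrane protein abundant in macrophages, rose by 2.25 (deposited standard error 0.15), the protease gene Ctss by 2.21 (0.19), the acid lipase gene Lipa by 1.56 (0.12) and the mannosidase gene Man2b1 by 1.28 (0.12). The macrophage list shares 3 listed members with the lysosome list and was higher beside it. The call was lost among genes with an absolute log2 fold change of at least 1 (adjusted p = 0.096) and against unmatched random lists (adjusted p = 0.37), and otherwise ranged down to 9.7e-06.

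Listed interferon-response genes were higher, with 21 of 21 listed members of 43 genes raised and a median log2 fold change of 1.36 (Fisher's exact test, adjusted p = 3.1e-05). The antiviral synthetase genes Oas2 and Oas1a rose by 3.89 (deposited standard error 0.38) and 2.20 (0.30), the GTPase gene Gbp2 by 1.36 (0.20) and the immunoproteasome gene Psmb8 by 1.3 (0.18) in the authors' deposited table. The interferon members Gbp4 and Gbp6 lie within 2 Mb of Spp1. Genes of the major histocompatibility complex and antigen presentation rose in 10 of 10 listed members of 20, with a median of 1.16 (Fisher's exact test, adjusted p = 0.0072). H2-K1, a class I heavy chain, rose by 1.25 (0.11), H2-T23 by 1.29 (0.18), B2m, the class I light chain, by 1.06 (0.18) and Tapbp, the tapasin gene, by 0.68 (0.12) in the authors' deposited table. The antigen presentation call was lost in 6 of 10 alternatives (adjusted p from 0.0033 to 0.31) and the interferon call in 2 of 10 (3.6e-05 to 0.24), both with the macrophage markers higher beside them.

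Listed reactive astrocyte genes leaned higher, with 18 members raised and 3 lowered of 38 genes and a median log2 fold change of 1.29 (Fisher's exact test, adjusted p = 0.0091). Lcn2, a secreted lipocalin, rose by 3.33 (deposited standard error 0.26), the metalloreductase gene Steap4 by 2.96 (0.23) and Cd14, a co-receptor for bacterial lipopolysaccharide, by 2.13 (0.14) in the authors' deposited table. Gfap, the intermediate filament gene of astrocytes, rose by 0.66 with a deposited standard error of 0.16, while Sphk1, Timp1 and Clcf1 fell, with log2 fold changes of -1.26, -1.05 and -0.79 in the authors' deposited table. The macrophage markers were higher beside this list too, with 25 of 25 listed members raised. Of the listed reactive astrocyte genes, 11 are on another list, and without genes on more than one list the call was lost (adjusted p = 0.060). It was also lost at an absolute log2 fold change of at least 1 and against unmatched random lists, with adjusted p from 0.0041 to 0.080 over 10 alternatives.

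Astrocyte identity genes showed no lean, with 6 higher and 4 lower of 27 genes (Fisher's exact test, adjusted p = 1). Gjb6, a connexin gene, rose by 4.28 (deposited standard error 0.37) and Aqp4, the main water channel of astrocytes, by 1.15 (0.16) in the authors' deposited table. S100b, a calcium-binding protein of glia, fell by 1.82 (0.15) and Fabp7, a fatty acid carrier of radial glia and immature astrocytes, fell by 1.23 (0.10) in the authors' deposited table.

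Listed markers of other neural cells were mostly lower in the knockout. Oligodendrocyte lineage genes gave 16 lower and 2 higher of 20 genes, with a median log2 fold change of -2.59 (Fisher's exact test, adjusted p = 7.6e-04). Mbp, which encodes a major myelin protein, had a log2 fold change of -2.46 (deposited standard error 0.16), and Cspg4, the NG2 proteoglycan of precursor cells, of -2.33 (0.14) in the authors' deposited table. The exceptions were Cldn11, a tight junction gene that rose by 2.93 (0.15), and Pdgfra, a growth factor receptor gene that rose by 0.85 (0.17), in the authors' deposited table. Schwann cell markers fell in 10 of 10 listed members of 14, with a median of -2.84 (Fisher's exact test, adjusted p = 0.0012), and 4 of them are on another list. Erbb3, a neuregulin receptor gene, fell by 2.24 (0.23) and Foxd3, a neural crest transcription factor, fell by 7.05 (0.74) from an implied wild-type mean of 176 to 1.33 in the authors' deposited table. The oligodendrocyte call was lost among genes with a mean of at least 100 (adjusted p = 0.11, from 7.8e-05 over 10 alternatives), and the Schwann cell call held in all 10.

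Neuron markers fell in 11 of 11 listed members of 23 genes, with a median log2 fold change of -1.43 (Fisher's exact test, adjusted p = 7.6e-04), a call that held in all 10 alternatives. Thy1, a surface glycoprotein of retinal ganglion cells, stood at -1.26 (deposited standard error 0.13), the growth cone gene Gap43 at -1.03 (0.18) and Elavl3, a neuronal RNA-binding protein, at -2.85 (0.30) in the authors' deposited table. Müller glia and retinal progenitor markers fell in 9 of 9 listed members of 18, with a median of -1.57 (Fisher's exact test, adjusted p = 0.0025). The eye-field transcription factor genes Six3 and Lhx2 stood at -1.57 (0.13) and -1.17 (0.14), and Rax at -5.00 (0.63), in the authors' deposited table. The Müller glia call was lost among genes with a mean of at least 100 (adjusted p = 0.053) and with the Wald statistic (adjusted p = 0.14), and was otherwise as low as 0.0029.

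Listed cell cycle genes were lower in the knockout. All 28 listed members of 43 genes fell, with a median log2 fold change of -0.91, a 1.88-fold lower level (Fisher's exact test, adjusted p = 5.9e-09). Plk1, a mitotic kinase, stood at -1.47 (deposited standard error 0.19), Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, at -1.26 (0.16), the cyclin gene Ccnb1 at -1.17 (0.13) and the spindle midzone gene Prc1 at -0.90 (0.12) in the authors' deposited table. Beside these genes the macrophage markers were higher (25 of 25 listed), and the listed oligodendrocyte (16 of 18), Schwann cell (10 of 10) and neuron markers (11 of 11) were lower. The call held in all 10 alternatives, with adjusted p up to 0.019.

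Among nuclear genes of oxidative phosphorylation, 22 of 75 were listed and all 22 were lower, with a median log2 fold change of -0.82 (Fisher's exact test, adjusted p = 3.7e-07). The complex I genes Ndufa4, Ndufs4 and Ndufa5 had log2 fold changes of -0.94 (deposited standard error 0.13), -0.94 (0.18) and -0.74 (0.17), and Cox7a2 of complex IV of -0.95 (0.23), in the authors' deposited table. Members had a median transcript length of 913 bases against 3432 for the other listed genes, and genes with short transcripts were more often lower than genes with long ones across all listed genes (57.1% against 36.5%, shortest and longest 20% by length). The macrophage markers were higher, and the oligodendrocyte, Schwann cell and neuron markers lower, beside this list too. The call was lost at an absolute log2 fold change of at least 1 (adjusted p = 0.53), with the Wald statistic and against unmatched random lists, and its lowest value was 3.8e-07. The mitochondrial genome had 1 listed gene, mt-Nd4l, which rose by 0.62 (0.17) in the authors' deposited table (Fisher's exact test, adjusted p = 1).

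Extracellular matrix genes leaned lower, with 23 lower and 6 higher of 49 genes and a median log2 fold change of -0.78 (Fisher's exact test, adjusted p = 9.5e-04). Fbln2, a fibulin gene, fell by 2.53 (deposited standard error 0.16) and Ncan, a brain proteoglycan, fell by 1.69 (0.12) in the authors' deposited table. The higher members included the small proteoglycan gene Dcn, up by 2.87 (0.16), and Fbln1, up by 1.86 (0.11), with Lum, Col3a1, Lama1 and Lama4, in the authors' deposited table. Trophic factors also leaned lower, 16 against 4 of 40 genes, with a median of -1.03 (Fisher's exact test, adjusted p = 0.0066). Ccn2, a matricellular growth factor, stood at -1.57 (0.11), Fgf1 at -1.49 (0.13) and Hbegf at -1.40 (0.12) in the authors' deposited table. Igf2, an insulin-like growth factor, rose by 3.38 (0.18) in the authors' deposited table, with Igf1, Cntf and Hgf also higher. The same cell-type markers, of macrophages upward and of oligodendrocytes, Schwann cells and neurons downward, moved beside the matrix and trophic factor lists. The matrix call was lost against unmatched random lists (adjusted p = 0.089, from 1.4e-05), and the trophic factor call in 3 of 10 alternatives (adjusted p from 0.0038 to 0.14).

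**Figure D2:**
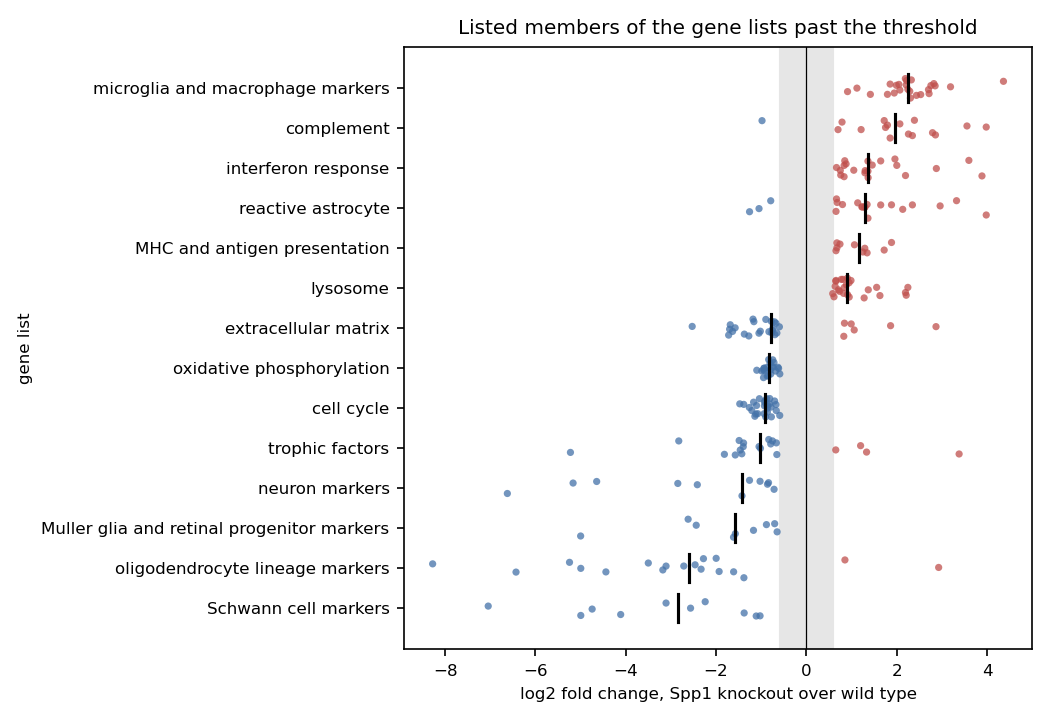
Log2 fold change of knockout over wild type (x axis) of each listed member of the 14 gene lists past the threshold (y axis), from the authors' deposited table. Points are genes, black bars are medians, which run from -2.84 for Schwann cell markers to 2.25 for microglia and macrophage markers, and the grey band holds fold changes below the limit of the table.

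The remaining lists did not pass Fisher's exact test, though 6 of them passed in some alternatives. Cytokines and chemokines and the family of Spp1 passed in 4 of 10 each, and phagocytosis receptors and bridging proteins in 3. Spp1 itself is 1 of the 2 listed members of its family, beside Dmp1. The passes of that list therefore rest partly on the deletion and lend no support. Early response genes passed in 2, and TGF-beta targets and pericyte and smooth muscle markers in 1 each. Cytokines and chemokines gave 16 higher and 5 lower (adjusted p = 0.15), among them Ccl9 (log2 fold change 3.50, deposited standard error 0.21) and Ccl6 (3.28, 0.26) in the authors' deposited table. Phagocytosis receptors and bridging proteins gave 11 and 3 (adjusted p = 0.18), with Cd36 at 2.46 (0.16) and Mertk at 1.49 (0.13) in the authors' deposited table. Lipid transport gave 11 higher and 2 lower (adjusted p = 0.10), early response genes 2 and 8 (0.10), cholesterol synthesis 0 and 3 (0.17), and glycolysis 3 and 0 (0.37). Pericyte and smooth muscle markers gave 2 higher and 6 lower (adjusted p = 0.25), endothelial markers 3 and 5 (0.59), fibroblast and meningeal markers 10 and 7 (0.86), pigment epithelium and melanocyte markers 5 and 2 (0.59), and lens and corneal markers 1 and 2 (0.70). The unfolded protein response gave 2 higher and 5 lower (adjusted p = 0.37), TGF-beta targets 5 and 8 (0.37), hypoxia genes 3 and 1 (0.72), integrins with Cd44 5 and 3 (0.81), matrix proteases with their inhibitors 5 and 7 (0.52), and the family of Spp1 0 and 2 (0.32). Photoreceptor markers had 0 listed members of 18 and were not tested.

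**Figure D3:**
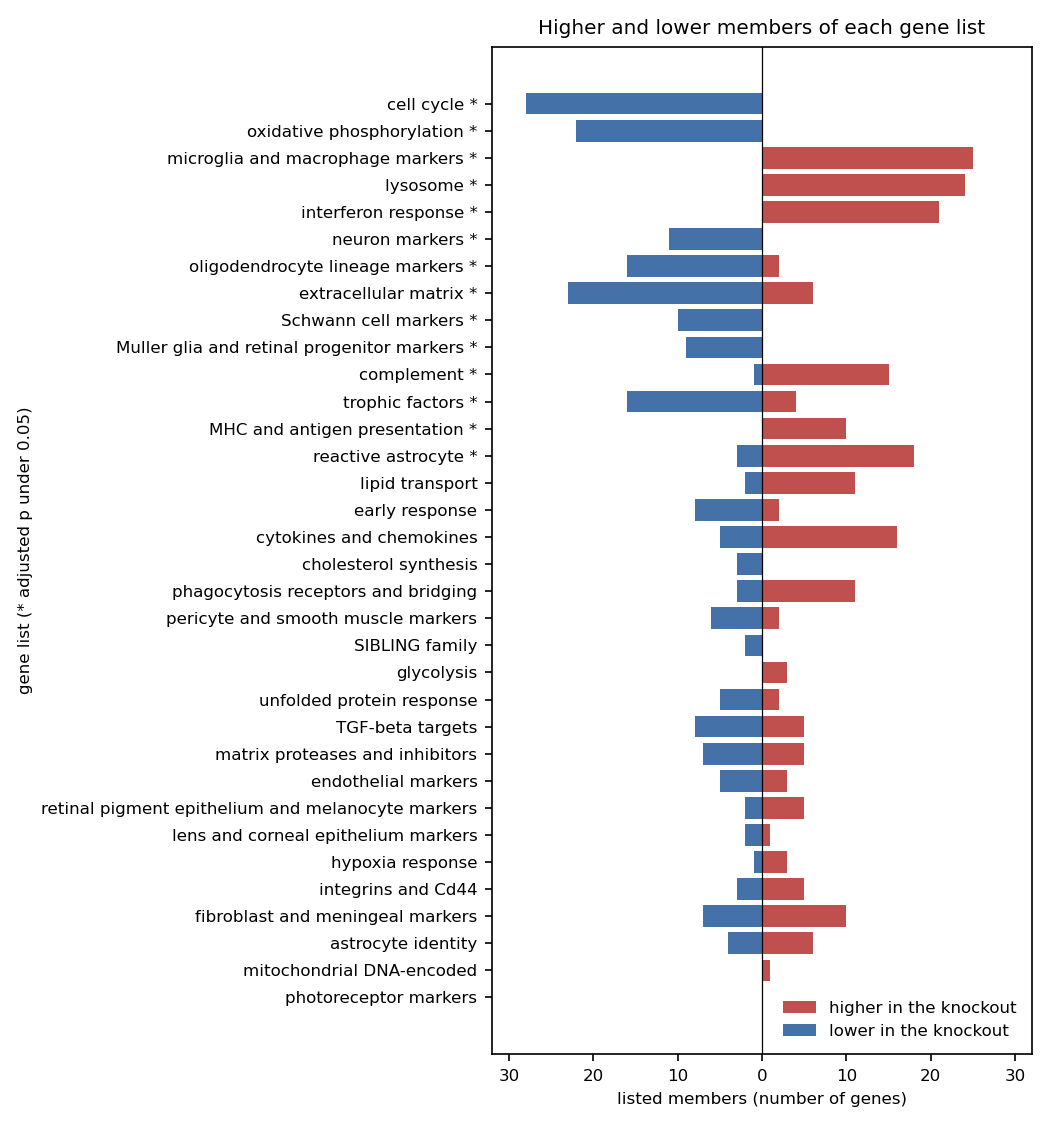
Number of listed members higher (red, right) and lower (blue, left) in the knockout for each of the 34 gene lists, from the authors' deposited table, with an asterisk at adjusted p under 0.05 by Fisher's exact test. Of the 14 lists past the threshold 6 lean higher and 8 lean lower, from 28 lower members for cell cycle to 25 higher members for microglia and macrophages.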

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

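Chosen after seeing the data were, for the lists, the limits on adjusted p and fold change, matched random lists with the median, matching on GC content and length, and leaving out shared genes, and, for the counts, leaving out marker or sex-linked genes and joint limits. The count of 3624 changed genes became 2101 at an absolute log2 fold change of at least 1 and 1714 with Bonferroni adjustment over the implied number of tested genes, both by construction. The share of higher genes, 54.9%, became 56.8% at adjusted p under 0.01, 61.2% at an absolute log2 fold change of at least 1, and 64.9% with a mean of at least 100 as well; the cause was not tested. Recomputing the Benjamini-Hochberg adjustment over the listed p-values kept 3624 by construction. Between 10 and 18 lists passed the threshold, against 14. Of the 14, 4 (cell cycle, microglia and macrophages, neurons, Schwann cells) passed in each alternative run and 10 lost the call in at least 1, while 6 others gained one under at least 1 setting and 0 changed direction. The family of Spp1, which includes the deleted gene, is among those 6. Matching on GC content and length, or leaving out macrophage markers (also chosen afterwards for the lists), lost 0 calls of the lists it tested. Among the other called lists, only complement and lysosome, with 3 each, shared listed members with the macrophage list. Leaving the markers out could therefore hardly change the remaining calls, and macrophage genes outside that list stayed in. The matching on GC content and length drew genes singly, whereas genes of a cell type or pathway move together. It therefore does not decide on a trend of the fold change with GC content or length. Unmatched random lists lost 6. Their power is unknown, since only matched random lists with the median were run on simulated tables. No paired analysis was possible because the authors' deposited table gives no values per sample. For the same reason leaving out samples, other splits of the samples, other normalizations, tools and pseudocounts, camera and fry were not run, and depth could not be weighed.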

Other observations

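The gene groups in this paragraph and the next were assembled after the values were seen, so their counts describe the genes picked and carry no test. Of 23 genes of the leptomeninges and arachnoid barrier, the membranes around brain and optic nerve, 16 were listed as higher in the knockout and 1 as lower, with a median log2 fold change of 2.93. In the authors' deposited table the transporter genes Slc6a20a and Slc6a13 rose by 6.74 (deposited standard error 0.82) and 6.73 (0.95), from implied wild-type means below 1, and the connexin gene Gjb2 by 2.63 (0.23), while Crabp2 fell by 1.18 (0.35). Ptgds, Slc22a8, Igf2, Gjb6 and Cldn11 belong to this group too, and 11 of its listed members are on the lists fixed beforehand, so it is not independent of them. The fixed list of fibroblast and meningeal markers had 10 higher and 7 lower members. Listed Toll-like receptors were higher in 8 of 8 (median 2.40), led in the authors' deposited table by the endosomal receptor genes Tlr8 (4.03, 0.23) and Tlr13 (3.10, 0.15). Listed Fc gamma receptor and Ms4a genes were higher in 12 of 12 (median 3.25), including Ms4a7 at 3.32 (0.19) in the authors' deposited table.

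Ribosomal protein genes present in the table were lower, 20 of 20 for the cytosolic ribosome (median log2 fold change -0.75) and 13 of 13 for the mitochondrial one (median -0.77). Of 27 imprinted genes 5 were listed as higher and 10 as lower. In the authors' deposited table Mest fell by 3.11 (deposited standard error 0.17) and Peg10 fell by 1.24 (0.20), while Cdkn1c rose by 2.42 (0.47). The share of lower genes rose from 31.2% to 66.5% from the fifth of listed genes with the lowest GC content to the fifth with the highest, and fell from 57.1% to 36.5% from the shortest to the longest transcripts. Within 2 Mb of Spp1, leaving out Spp1 itself, 8 of 30 protein-coding genes were listed (26.7%, against a median of 15.4% over windows of that size, each without its central gene, percentile 91.2), and within 10 Mb 33 of 201 (16.4%, percentile 53.0). Of those 8 genes, 5 are Gbp genes, all 5 higher, and 2 of them (Gbp4 and Gbp6) are also counted on the interferon list. Gm28437, a predicted gene, fell by 12.57 (deposited standard error 1.59) in the authors' deposited table.

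All tests in this part were chosen after the patterns were seen; for transcript length and GC content alone, the outcome that would count for or against was written down before the test was run. Listed macrophage markers were higher in the knockout, as were the listed lysosomal and interferon genes and 15 of 16 listed complement genes. A single change in the share of microglia and macrophages would move every marker alike, but the fold changes of the 25 markers differed between genes with an SD of 0.744 on the log2 scale against a median standard error of 0.195 (Cochran's Q, chi-square p = 7.8e-93). Among the 21 markers with a mean of at least 1000 the SD was 0.748, so low counts do not account for it. A changed share together with a changed state of these cells may contribute and was not tested, nor was an effect of genotype on astrocytes themselves, since the table has no samples and no cell types.

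Of 6 listed Y-linked genes 5 were higher in the knockout, and Gm21748 fell by 1.86 (deposited standard error 0.22) in the authors' deposited table. All 4 broadly expressed Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty) rose by more than 1 plus 2 standard errors, which is consistent with a larger share of male cells in the knockout cultures. Reads of X-linked copies counted on their Y-linked partners at one rate in both genotypes would reach the Y-linked genes in wild type too, where the level of each of the 4 was at most 1.66% of that in the knockout (highest upper 95% bound 2.60%) and the implied mean of Ddx3y and of Eif2s3y was 0.16 in the authors' deposited table. A rate that differed between genotypes was not tested, since only 1 of the 4 X-linked partners was listed, Kdm5c at -0.62 (deposited standard error 0.11) in the authors' deposited table. Unless that rate differed, the wild-type cultures held few male cells beside the knockout cultures, and sex and genotype are confounded for every gene above. How many of the changes follow sex was not tested.

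The 22 listed genes of oxidative phosphorylation, of 75, were lower in the knockout. Random lists matched on transcript length and mean count held a median of 16 lower members of 22. Their median log2 fold change was -0.71, against -0.82 for the members. The share of the 10000 lists with all 22 lower was 0.0002, so genes drawn 1 by 1 at these lengths seldom all fell. Genes of one pathway move together, which makes this share too small, so it does not decide on a trend of the fold change with transcript length. How much of the size follows length cannot be read from a table filtered on fold change. For a trend of the fold change with GC content, matched lists held a median of 9 lower members, and the share with all 22 was 0.0001, the smallest the draws can give. Members had a median GC content of 49.7% against 49.9% for the rest. The matched lists thus resembled draws from the rest of the table, and the matching on GC content adds little. An effect of genotype, of sex or of cell make-up on these genes stays open and was not tested.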
